A study of Homo sapiens with 2 samples.

How the data were processed

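Total RNA of HL-60 cells was extracted with Trizol and treated with DNase, per the labels' protocols, which also state that the cells were grown in medium with 10% serum at 37 °C and 5% CO2. From each sample 200 ng of RNA was amplified and biotin-labelled with NuGEN kits and hybridised to an Affymetrix Human Gene 1.0 ST array, per the labels' protocols. The deposited values are log2 signals per probe set made by the authors with RMA (background correction, quantile normalization and a robust summary over probes), per the submitters' processing notes; the software, its version and which arrays were normalized together are not given in the sources used here. The log base is not stated. Base 2 was taken because it is RMA's own, and because the highest value, 12.9, would as a natural logarithm stand for 407306, above the limit of 65535 of a 16-bit scanner. No scanner files were used here, so background correction, probe affinity, detection p-values and scan batches could not be examined. RMA brings the distributions of the arrays together, so a global difference in RNA content cannot be seen.

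Of the 32321 probe sets, 19158 carried 1 gene symbol in the platform annotation, 1388 carried several and 11775 were not listed there. Only the first kind was named. Symbols were updated through Entrez IDs, of which 19128 of 19158 were found in the RefSeq gene table (assembly GRCh38.p14, used for names only), giving 18404 genes. The 637 genes with more than 1 probe set took the mean of their log2 values. No coordinates are given because the build of the array annotation is not stated. Probe sets equal on both arrays numbered 1628 (5.04%), among them 7.27% of the probe sets in the lowest 10% of signals and 0.371% of those in the highest 10%.

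The design has 1 group of 2 arrays, so no test between groups exists and no p-values were computed. The lists, thresholds and naming rule were fixed before the data were examined. A gene was called above background where its signal exceeded the 95th percentile of the olfactory receptor genes on both arrays, and the same percentile of a second set (keratin-associated proteins, bitter taste receptors and beta-defensins) checked that threshold. For each of 28 gene lists (26 with named members, and the replication-dependent histones and small nucleolar RNAs by symbol), members above background were counted and the list's median was placed among 10000 random gene lists of the same size, on each array. A list stood apart where its median lay outside the central 95% of random lists, on the same side on both arrays. For the difference between arrays, random lists were matched on mean signal in 10 bins. Percentiles describe these 2 arrays and treat genes as exchangeable. The matched procedure was tested on simulated data with 18404 genes and the observed spread of the difference between the arrays. Of 25 lists of 12 genes it called 1 with no shift, 12 with a shift of 0.25, 24 with a shift of 0.5 and 25 with a shift of 1 (log2). The simulated differences were independent between genes with the same SD for all, and fewer than 10000 random lists were drawn. Lists whose members vary together were not simulated.

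The genes named were 17 fixed genes, the 2 highest and the lowest measured member of each of the 26 lists, the 5 genes with the highest signal, and the 5 with the largest difference between arrays among genes above background on at least 1 array. Of the 17 fixed genes 15 are reported, and the others, like list members without a probe set of their own here, are not reported here. Alternatives were quantile normalization of the 2 arrays to each other, removal of a loess trend of the difference on the signal, the highest probe set per gene, a 99th percentile threshold, the second background set as threshold, each array alone, the list's mean in place of its median, random lists without background genes, and a filter on dim genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.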

Results

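Gene expression was measured in HL-60, a human promyelocytic leukaemia cell line, on 2 Affymetrix Human Gene 1.0 ST arrays labelled as replicates 1 and 2 of the wild-type line. The study's stated subject is how RNAs bound by DNA methyltransferase DNMT1 relate to DNA methylation and gene expression, and these arrays give the expression level of the untreated cells. They form 1 group, so no treatment or genotype is compared. The table held 32321 probe sets on each array, and the median signal was 3.02 on replicate 1 and lower by 0.02 on replicate 2 (log2, RMA). The 18404 genes with a name of their own are described as mean ± SD of the log2 signal over the 2 arrays (n = 2). The number of arrays limits the precision, and the labels do not say whether the replicates came from separate cultures, so the spread may be technical.

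The 2 arrays ranked genes alike but were not copies of each other. Across genes, which are not independent replicates, the signals correlated with Pearson's r = 0.974 and Spearman's rho = 0.965. The olfactory receptor genes, taken below as background, still correlated between the arrays (r = 0.767, rho = 0.760). Part of the agreement therefore need not reflect expression. The difference between the arrays had an SD of 0.39 over genes, which corresponds to an SD of 0.28 per array, or 1.21-fold. A total of 361 genes (1.96%) differed by more than 1 on the log2 scale, 199 of them higher on replicate 2 and 162 higher on replicate 1. For 962 genes (5.23%) the deposited values were exactly equal on both arrays, so an SD near 0 for a single gene does not show a smaller error, and 0.28 is the better guide.

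Background was set from 359 olfactory receptor genes, sensory receptors that a myeloid line is not expected to use. Their 95th percentile was 2.98 on replicate 1 and 2.88 on replicate 2, and 10262 genes (55.8%) lay above it on both arrays. A second set of 115 genes of other restricted families gave a higher background: 37 of them (32.2%) passed the olfactory threshold. The 95th percentile of that second set was 5.41 on replicate 1 and 5.23 on replicate 2, and 3137 genes (17.0%) exceeded it on both arrays. Genes between these limits are therefore described as above the olfactory threshold only. A probe set's signal also depends on its probes, so the levels of different genes are not relative transcript abundances.

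DNMT1, the maintenance DNA methyltransferase, read 6.84 ± 0.24 and was above both thresholds on both arrays. The de novo methyltransferase DNMT3A read 4.75 on both arrays, above the olfactory threshold only, while DNMT3B (2.89 ± 0.09) passed it on replicate 2 only and DNMT3L (2.70 ± 0.15) on neither array. UHRF1, which recruits DNMT1 to replicating DNA, read 3.40 ± 0.26, but its 2 probe sets lay 1.99 apart. The dioxygenases TET1 (4.59 ± 0.05) and TET3 (4.61 ± 0.04) passed the olfactory threshold, and TET2 (6.01 ± 0.02, with 2 probe sets 1.09 apart) passed both. The methyl-CpG binding protein MBD2 reached 6.53 ± 0.50. Of 16 measured members of this list, 13 were above the olfactory threshold and 7 above the second. The median of the list lay at percentile 99.6 of random gene lists of the same size on replicate 1 and at percentile 98.9 on replicate 2.

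The 7 genes of the C/EBP list were all above the olfactory threshold. CEBPZ alone (7.25 on both arrays) was above the second, and it shares the name but is not a basic leucine zipper factor like the others. CEBPA, a regulator of granulocyte development, read 4.01 ± 0.29. CEBPE, which acts later in granulocyte maturation, read 4.62 ± 0.18, CEBPB 3.83 ± 0.11, CEBPD 4.11 ± 0.45, CEBPG 5.55 ± 0.21 and DDIT3 3.54 ± 0.45. The list did not stand apart from random lists (percentiles 68.9 and 86.2). Among 10 haematopoietic transcription factors, 8 passed the olfactory threshold and 3 the second. MYB, a progenitor factor, was the highest at 9.41 ± 0.17, followed by CBFB at 6.99 ± 0.46. SPI1, which encodes PU.1, read 4.90 ± 0.16, and IRF8, a monocyte and dendritic cell factor, was not above background (1.62 ± 0.04). This list stood at percentiles 97.4 and 98.8, above the central 95% of random lists on replicate 2 only. MYC, which is amplified in HL-60, read 8.42 ± 0.29 and passed both thresholds. The cell cycle inhibitor locus CDKN2A read 3.38 ± 0.14, above the olfactory threshold only.

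Most granule genes of the promyelocyte stage passed the olfactory threshold, and those of later stages largely did not. Of 11 genes of the primary granule list, 9 were above the olfactory threshold and 5 above the second. The list also holds MS4A3, which encodes a membrane protein, and RNASE2, known chiefly from eosinophil granules. The proteoglycan SRGN (9.13 ± 0.17) and the serine protease CTSG (8.12 ± 1.24) were the highest, and the defensin DEFA4 (1.41 ± 0.50) was the lowest and not above background. The primary granule list stood at percentile 100 on replicate 1 and 96.3 on replicate 2, so it lay above the central 95% on 1 array only. Of 13 secondary and tertiary granule genes, 3 were above the olfactory threshold and 0 above the second. PGLYRP1 (3.94 ± 0.63) and LCN2 (3.53 ± 0.23) were the highest and the collagenase MMP8, at 1.46 on both arrays, the lowest. Of 12 mature neutrophil markers, 1 was above the olfactory threshold on both arrays, the G-CSF receptor gene CSF3R (4.56 ± 0.36), and 2 were without replicate 1. Of the calprotectin genes, S100A9 (3.01 ± 0.23) passed on replicate 2 only and S100A8 (1.54 ± 0.29) on neither array. Of 11 monocyte and macrophage markers, 1 passed, the lysosomal gene CD68 (4.35 ± 0.35), while FCN1 (2.86 ± 0.06) and the scavenger receptor MSR1 (1.27 ± 0.10) did not. The secondary granule, mature neutrophil and monocyte lists each lay below percentile 2.5 of random lists on both arrays.

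Of the lists of markers of other lineages, only that of T and NK cells stood below random lists on both arrays; the other six did not stand apart by their medians, although the erythroid and epithelial lists did by their means. Some of these counts rested on 1 array: without replicate 1, the markers above the olfactory threshold were 5 for both the erythroid and the megakaryocyte lists, and without replicate 2 they were 3 for the epithelial, stromal and liver list. Among 10 stem and progenitor markers, 4 passed the olfactory threshold, led by GATA2 (4.63 ± 0.12) and FLT3 (4.59 ± 0.58), and PROM1 was the lowest (1.59 ± 0.10). Of 11 erythroid markers 3 passed. GATA1 read 3.85 ± 0.27, KLF1 3.71 ± 0.01 and the embryonic globin gene HBZ 1.51 ± 0.08. Of 9 megakaryocyte markers 3 passed, with GP6 at 3.80 ± 0.19, GP9 at 3.20 ± 0.11 and VWF at 2.24 on both arrays. Of 15 T and NK cell markers 4 passed, with NKG7 at 4.34 ± 0.13, CD5 at 3.26 ± 0.08 and KLRD1 at 1.51 ± 0.21. This list lay below percentile 2.5 on both arrays, a call that was lost with the highest probe set per gene. Of 9 B cell markers 4 passed, and IGLL1, a surrogate light chain gene, was above the second threshold as well (6.27 ± 0.61), while CD79B read 3.26 ± 0.10 and CR2 1.64 ± 0.16. Of 8 eosinophil, basophil and mast cell markers 3 passed. The eosinophil granule gene PRG2 exceeded both thresholds (7.71 ± 0.34), EPX read 3.54 ± 0.57 and IL5RA 1.66 ± 0.04. Of 15 epithelial, stromal and liver markers, 1 passed, COL1A1 (3.69 ± 0.09), whereas APOA1 (2.92 ± 0.36) passed on replicate 1 only as the mean of its 2 probe sets (2.48 and 3.35) and on both arrays by the higher of them, and EPCAM (1.45 ± 0.04) on neither array.

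**Figure D1:**
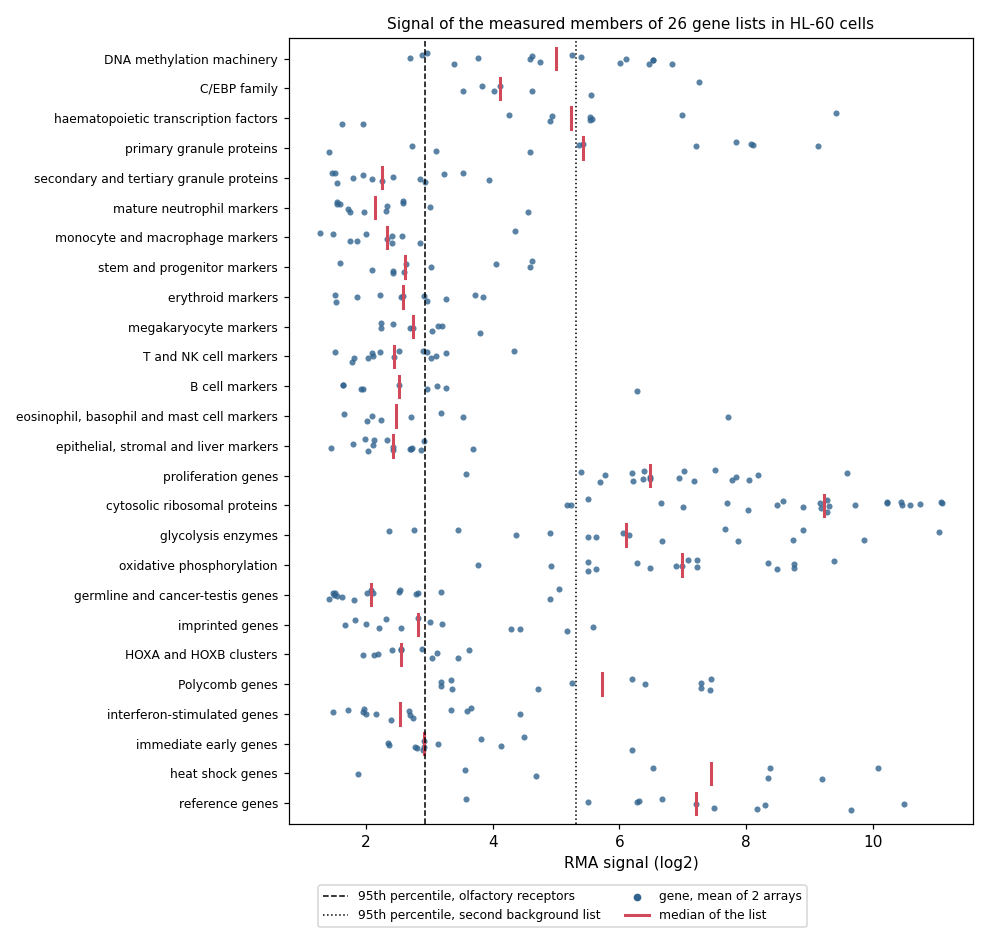
RMA signal (log2, x axis) of each measured member of the 26 gene lists with named members (y axis); points are means of the 2 arrays, red bars list medians, and dashed and dotted lines the olfactory and second background thresholds averaged over the arrays. All 19 proliferation genes and 24 ribosomal protein genes lie right of the dashed line, whereas most mature neutrophil and monocyte markers lie left of it.

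Proliferation, translation and core metabolic genes stood above random gene lists. All 19 proliferation genes passed the olfactory threshold and 18 the second. The exception was CDK1 (3.58 ± 0.08), while the thymidylate synthase gene TYMS read 9.60 ± 0.12 and the topoisomerase gene TOP2A 8.19 ± 0.24. All 24 measured ribosomal protein genes passed the first threshold and 21 the second, from RPL32 (5.18 ± 0.11) to RPL27 (11.08 ± 0.10) and RPL30 (11.10 ± 0.27). Of 16 glycolysis genes 14 passed. GAPDH read 11.05 ± 0.13 and LDHB 9.87 ± 0.09, but HK1 was not above background (2.37 ± 0.01). All 17 oxidative phosphorylation genes passed, with COX5A at 9.39 ± 0.06, ATP5F1A at 8.76 ± 0.02 and UQCRC1 at 3.77 ± 0.06. All 12 Polycomb genes passed, with the histone-binding RBBP4 (7.45 ± 0.38) and RBBP7 (7.43 ± 0.07) highest and CBX2 lowest (3.18 ± 0.20). Of 8 heat shock genes 7 passed, including HSPA8 (10.08 ± 0.13) and HSPD1 (9.19 ± 0.05), whereas the stress-inducible HSPA6 did not (1.88 ± 0.17). All 11 reference genes passed, from PPIA (3.58 ± 0.19) to ACTB (9.65 ± 0.13) and EEF1A1 (10.50 ± 0.34). These 7 lists and the DNA methylation machinery were the 8 of 28 lists whose median lay above the central 95% of random lists on both arrays. The 5 genes with the highest signal were RPL38 (11.11 ± 0.23), RPL30, RPL27, GAPDH and RPS20 (10.96 ± 0.09). Ribosomal protein genes and GAPDH have many processed pseudogenes, so their signals are uncertain where probes match more than 1 copy.

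Germline genes were mostly not above background, and imprinted, HOX, interferon-stimulated and immediate early genes were so in part. Of 17 germline and cancer-testis genes, which promoter methylation commonly silences in somatic cells, 3 passed the olfactory threshold and 0 the second. MAGEB2 (5.05 ± 0.15) and CTAG2 (4.91 ± 0.06) were the highest, MAGEA4 was the lowest (1.42 ± 0.06), and the list lay below percentile 2.5 on both arrays. Of 13 imprinted genes 6 passed, with MEST at 5.58 ± 0.50, GRB10 at 5.17 ± 0.74 and NDN at 1.66 ± 0.18. Of 11 measured HOXA and HOXB genes 3 passed, and 5 without replicate 1. HOXA2, the only HOXA gene measured, passed on replicate 2 only, so the count mainly describes HOXB genes. HOXB8 read 3.62 ± 0.06, HOXB4 3.46 ± 0.45 and HOXB6 1.95 ± 0.12. Of 14 interferon-stimulated genes 4 passed, with IFI6 at 4.43 ± 0.29, ISG15 at 3.66 ± 0.24 and IFI44 at 1.49 ± 0.39. Of 12 immediate early genes 5 passed, and 8 without replicate 1. EGR1 was the only one above the second threshold (6.19 ± 0.61), while JUNB read 4.49 on both arrays and FOS 2.34 ± 0.20. Of 56 replication-dependent histone genes, near-identical copies that can share probes, 31 passed. Of 192 small nucleolar RNAs 77 passed, and their list lay at percentile 0 on both arrays.

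The 2 arrays differed in named gene groups and not only gene by gene. Genes of the primary granule list were lower on replicate 2 than on replicate 1 in 9 of 11 cases. Their median difference was -0.73 on the log2 scale, or -1.10 among members above background on both arrays. The largest differences were those of CTSG (8.99 on replicate 1, 7.24 on replicate 2) and of LYZ (6.50 and 4.24), PRTN3 (7.95 and 6.47), RNASE2 (8.80 and 7.37, uncertain because of a closely related pseudogene), MS4A3 (5.98 and 4.88) and MPO (8.21 and 7.48), the last 5 named after their values were seen. ELANE (4.47 and 4.71) and AZU1 (3.01 and 3.19) went the other way. Glycolysis genes were lower on replicate 2 in 13 of 16 cases (median difference -0.43), as were 12 of 17 oxidative phosphorylation genes (-0.31), 119 of 192 small nucleolar RNAs (-0.17, or -0.08 after quantile normalization and -0.07 after loess) and 5 of 8 eosinophil, basophil and mast cell markers (-0.39). Replication-dependent histones were higher on replicate 2 in 41 of 56 cases (0.27), haematopoietic transcription factors in 7 of 10 (0.26) and mature neutrophil markers in 9 of 12 (0.22), although 11 of those 12 were not above background. Each of these 8 median differences lay outside the central 95% of 10000 random gene lists matched on signal, but that of the haematopoietic transcription factors no longer did after quantile normalization (percentile 95.3) or loess (percentile 95.7). By chance 1.4 of the 28 lists would, and members of a list vary together, which random lists leave out. With 1 array on each side the differences have no replicate check.

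**Figure D2:**
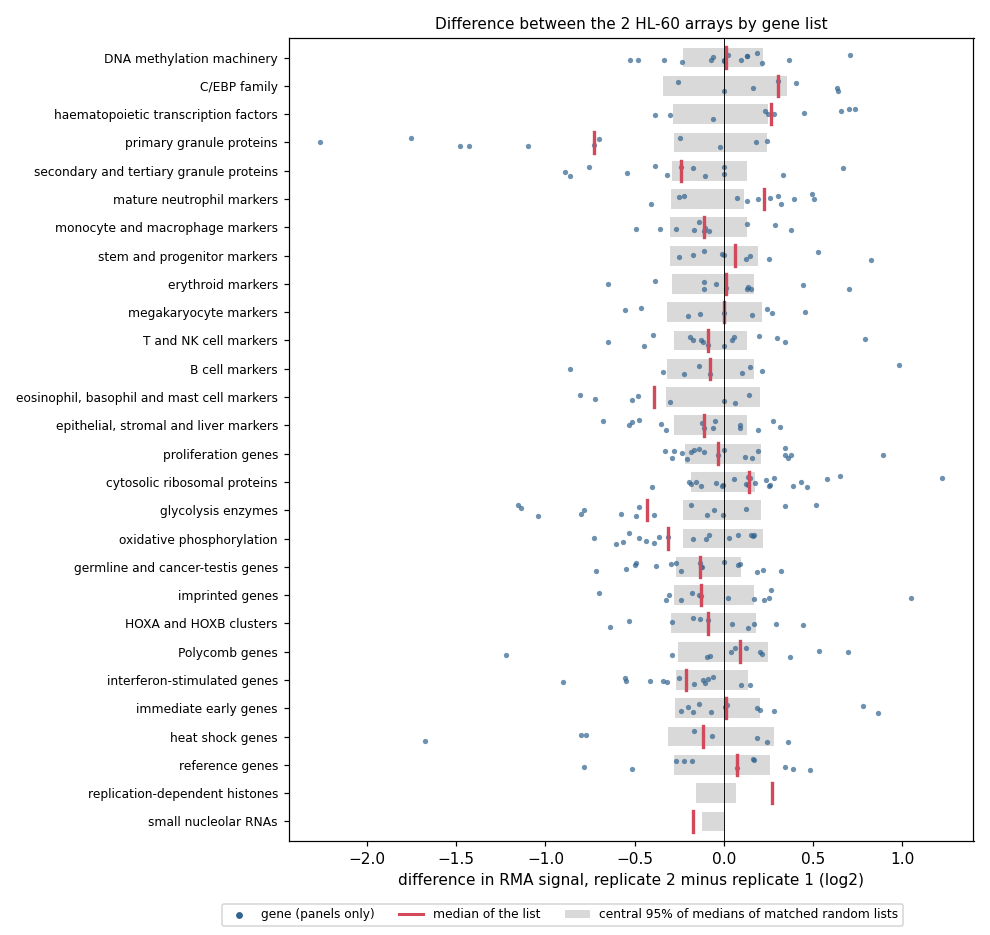
Difference in RMA signal between the 2 arrays (replicate 2 minus replicate 1, log2, x axis) for the 28 gene lists (y axis); points are genes of the lists with named members, red bars list medians, and grey bars the central 95% of medians of random lists matched on signal. The primary granule median of -0.73 lies farthest from its grey bar, and histones (0.27) lie to the right of theirs.

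The 5 largest differences among genes above the olfactory threshold on at least 1 array were those of NT5C3A, LINC00652, ZNF814, CEP19 and ABCA1. The nucleotidase gene NT5C3A read 6.20 on replicate 1 and 2.48 on replicate 2, the latter below background. The other four were higher on replicate 2: LINC00652 read 1.41 and 4.32, ZNF814 2.34 and 5.15, CEP19 4.05 and 6.51, and the cholesterol transporter gene ABCA1 2.59 and 5.01 on replicates 1 and 2. Only CEP19 was above background on both arrays.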

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

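Signal also appeared in probe sets that the named-gene comparisons left out. Of the 11775 probe sets not listed in the platform annotation, 3828 (32.5%) exceeded the olfactory threshold on both arrays and 1608 the second threshold. Of the 1388 probe sets with several gene symbols, 797 (57.4%) exceeded the olfactory threshold and 302 the second.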

How the results depend on the processing

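No paired analysis was possible because all arrays belong to 1 group. Of 36 recomputed main values, 32 stayed within 1.5 times the reported count or within the spread between replicates, and 4 moved. With the second background set as threshold the genes above background numbered 3137 in place of 10262, and named genes above background 28 in place of 70, since the signals of that set put the threshold higher; the member count moved by over 1.5 times for 22 of 28 lists. At the 99th percentile of the olfactory receptors it did so for 10, and the secondary and tertiary granule, erythroid, HOX and epithelial lists fell to 0 members above background; without replicate 1 it did so for 5 lists and without replicate 2 for 1. With genes above background only, 211 in place of 361 genes differed by more than 1 between the arrays, because fewer genes were compared. With the list's mean in place of its median, 10 in place of 6 lists were lower than random lists, the HOX, epithelial, erythroid and interferon-stimulated lists joining the reported 6, and 10 in place of 8 were higher, the primary granule proteins and haematopoietic transcription factors joining the reported 8. On each array alone, 10790 to 11132 genes and 72 to 75 named genes were above background, 9 lists (8 of them the reported ones) were higher and 7 (6 of them the reported ones) lower than random lists. Of the 8 lists that differed between the arrays, 7 remained outside the random range after quantile normalization and after loess; the haematopoietic transcription factors did not (percentiles 95.3 and 95.7). With genes above background only, 8 lists differed, the secondary and tertiary granule proteins (median difference -0.54) replacing the mature neutrophil markers, of which too few were left. Quantile normalization moved the median difference of all genes from -0.04 to 0.00. No list called as different between the arrays changed sign; some median differences inside the random range did. With the highest probe set per gene, the T and NK cell markers were no longer lower than random lists (5 lists in place of 6), and the epithelial list had 2 members above background in place of 1. The median difference of the small nucleolar RNAs shrank to -0.08 after quantile normalization and -0.07 after loess, and that of the primary granule genes grew to -1.10 with genes above background only. The background correction and a slide block, which need scanner files, were not run.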

Other observations

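The tests on the granule and glycolysis genes were chosen after their differences had been seen. The amino acid response and hypoxia lists were chosen after the largest differences between the arrays had been seen, but left out the genes seen there, and their predictions were written before their values were computed.

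Genes of the amino acid response, which ATF4 drives when amino acids or protein folding become limiting, were higher on replicate 2. All 26 listed targets were above the olfactory threshold on both arrays, and 24 of 26 were higher on replicate 2, by a median of 0.65 on the log2 scale. The serine synthesis gene PSAT1 read 6.40 on replicate 1 and 7.57 on replicate 2, the cystine transporter gene SLC7A11 5.58 and 6.55, the transcription factor gene ATF5 6.31 and 7.27, and the mitochondrial folate enzyme gene MTHFD2 7.56 and 8.32. All 9 aminoacyl-tRNA synthetase genes of the list were higher on replicate 2, among them CARS1 (4.72 and 5.64), GARS1 (8.01 and 8.74) and SARS1 (5.94 and 6.73), with EPRS1 the least different (8.16 and 8.23). The exceptions were ASNS (7.59 and 7.30) and PHGDH (5.77 and 5.66). Genes that prompted the list were CTH (4.67 and 6.56), STC2 (3.81 and 5.58), ALDH1L2 (4.54 and 6.24) and NIBAN1 (4.01 and 5.64).

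A candidate explanation is that the cells of replicate 2 were in an amino acid response. The median difference of the unseen targets lay at percentile 100 of random lists matched on signal. Limited protein folding, or any other stress that acts through ATF4, cannot be told apart from limited amino acids by these genes. A difference that depends on signal level is argued against by the match on signal, since random lists of the same signal would share it. After a loess trend was removed the percentile was again 100 and the median difference 0.63, which adds little for the same reason. Effects of normalization unrelated to signal level were not tested. The prediction for a hypoxia response was not met, but the response is not excluded. The glycolysis genes, which hypoxia induces, were lower on replicate 2 in 13 of 16 cases, with the list at percentile 0.02. That fall was seen before the test was chosen. The 3 higher on replicate 2 included HK2 (5.90 on replicate 1 and 6.41 on replicate 2) and ENO2 (3.29 and 3.63). The hypoxia targets themselves decide nothing, since 7 were higher on replicate 2, such as SLC2A3 (3.88 on replicate 1 and 5.34 on replicate 2) and BNIP3L (5.54 and 6.61), and 6 on replicate 1, with their median at percentile 70.3. Culture density, medium age and any difference in RNA preparation between the 2 samples were not recorded in the labels and stay open. With 1 array on each side the pattern is a hypothesis.

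For the lower primary granule genes on replicate 2, a difference that depends on signal level is argued against by the match on signal. Random lists of the same signal would share it, and the list lay at percentile 0. That percentile is also how the pattern was found, so it is no separate test. After loess the percentile was again 0, which adds little for the same reason as above. Effects of normalization unrelated to signal level were not tested for the primary granule genes. Whether replicate 2 held more mature cells, which could also lower such genes, cannot be decided. The secondary granule, mature neutrophil and monocyte lists pooled lay at percentile 41.0, but 31 of their 36 genes were not above background. The mature neutrophil list alone lay at percentile 99.9. The secondary and tertiary granule genes above background, 3 of 13, went the other way (median difference -0.54, percentile 0.525). Both the granule and the amino acid patterns may come from 1 difference in culture state, which these arrays do not test.

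The background differed between gene families that a myeloid line is not expected to use. On both arrays, 31 of 68 keratin-associated protein genes (45.6%) exceeded the olfactory threshold, against 4 of 24 bitter taste receptors (16.7%), 2 of 23 beta-defensins (8.70%) and 7 of the 359 olfactory receptors themselves (1.95%). The split was made after the data were seen, and probe sequences were not used here.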
